A study of Arabidopsis thaliana with 40 samples.

How the data were processed

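RNA from pools of 5 whole rosettes of 18-day-old Arabidopsis thaliana plants was sequenced in 10 genotypes with 4 replicates each, per the labels. Per the labels' protocols, plants grew under 16 h light and 8 h dark at 23 °C and were harvested 6.5 h after dawn, RNA was treated with DNase on the column, and libraries were made with a stranded mRNA kit. Per the submitters' processing notes, the authors used Trimmomatic, aligned reads to TAIR10 with TopHat2 2.1.0, counted them per gene with HTSeq 0.6.1, and also used edgeR. The deposited values are one count per gene and library, as whole numbers, and all of the steps below start from them.

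The table held 33602 genes, 7160 of them with no count in any library, and 5 summary entries of the counting step, which were left out of library sizes and tests and made up 4.48 to 21.8% of a library. Gene symbols came from a reference table that matched 32835 locus tags and 19374 of the genes tested. That table is of the TAIR10.1 release, so no coordinates are given. 

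Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling (factors 0.958 to 1.08), filterByExpr by group, which kept 19490 genes, trended dispersion, and quasi-likelihood F-tests in a single fit of all 40 libraries with a mean per group. A gene was called at a Benjamini-Hochberg adjusted p < 0.05 within its comparison, with no minimum fold change. There were 17 comparisons of 2 groups and 3 interactions, the difference between the change from ref4-3 to a double mutant and that from WT to the single mutant. An interaction needs the second lesion without ref4-3 and was not analysed here for med5b-3. The comparisons, tests, gene lists and alternatives were chosen before the data were examined, except where a sentence says otherwise.

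The 22 gene lists held 362 genes, 327 of them tested: lignin and sinapate, flavonoid, repressor, secondary cell wall, Mediator, salicylic acid defence, jasmonate and ethylene, cold, clock, flowering time, iron deficiency, photosynthesis, auxin response, glucosinolate, brassinosteroid, xenobiotic, heat shock, senescence, root marker, flower marker, trichome and stomatal, seed marker. Lists were tested against the other genes with camera on voom values (limma 3.58.1) at the preset correlation, and again with an estimated one, with adjustment over the lists of each comparison. The rotation test fry served as an alternative, and it tests only whether a list moves in one direction on balance.

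Genes are named by a fixed rule. These are the 5 targeted genes, the 5 most increased and 5 most decreased called genes of each single mutant against WT and of each line against ref4-3 (3 and 3 elsewhere) among those with an average log2 CPM of at least 1 and no overlap between the groups' libraries, which chance gives for 2.86% of genes. Also named are up to 4 called members per list and direction in order of adjusted p, and any lignin, sinapate, flavonoid or repressor gene. A gene named in one comparison could be given in others.

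On simulated data with changes added to 200 genes per size, the same test called 48.0% of 1.25-fold, 91.0% of 1.5-fold, 95.5% of 2-fold and 99% of 4-fold changes in ref4-3 against WT, and 0.0544% of unchanged genes. For the med2 interaction these shares were 18.5, 68.0, 84.5, 97.0 and 0.0311%. Simulated lines with no effect or full return gave the scale for overlaps and for the share of genes called back. Alternatives were RLE or library size scaling, 2 other filters, fits of only the groups compared, DESeq2 1.42.0, limma-voom, a robust dispersion, other thresholds, a replicate block, and each library left out in turn. Added after the data were seen were fits without med2 ref4-3 replicate 1, without med2 replicate 2, and without both. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.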

Results

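Whole rosettes of 18-day-old plants were profiled in 10 genotypes with 4 libraries each: wild type (WT), the MED5b mutant ref4-3, the single mutants med2, med16 and med23, the double mutant med5ab, and 4 lines that carry ref4-3 with a second lesion, med2 ref4-3, med5b-3 ref4-3, med16 ref4-3 and med23 ref4-3. Depth ran from 3.78 M counts in genes (med2 replicate 2) to 21.94 M (WT replicate 4), with a median of 15.2 M. Values are counts scaled to library size by TMM (CPM), mean ± SD, n = 4 libraries. Changes are log2 fold changes ± standard error. Of 19490 genes, those called pass edgeR quasi-likelihood tests at a Benjamini-Hochberg adjusted p < 0.05, and the highest adjusted p is given beside several genes. Lists are tested with camera at a preset correlation, and then with the correlation estimated, written as if estimated. Marker lists not mentioned in a comparison had no called member. Genes named together without a list count stand for themselves alone. Pairs of values in parentheses give the mutant first, in CPM, and other values are log2 changes (± standard error). The second mutated genes of med2 ref4-3, med16 ref4-3 and med23 ref4-3 carry other alleles, or another pair of alleles, than the single mutants, per the labels, so genotype and allele differ together between these lines and the singles.

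MED2 fell in med2, to 2.01 ± 0.371 CPM from 3.99 ± 0.354 in WT, a log2 change of −1.04 ± 0.18 (adjusted p = 3.56e-05). In med5ab, MED5A fell to 21.3 ± 0.598 from 40.8 ± 5.15 CPM and MED5B to 5.77 ± 0.741 from 24.1 ± 0.723 (highest adjusted p = 3.66e-13). MED16 was at 1.06 ± 0.25 CPM in med16 against 21.1 ± 1.91 in WT (adjusted p = 1.13e-27). MED23 was at 0.868 ± 0.216 CPM in med23 against 34.9 ± 3.47 (adjusted p = 6.83e-30). The lines in the ref4-3 background kept more of these transcripts: MED2 was at 2.99 ± 0.2 CPM in med2 ref4-3 (adjusted p = 0.0480), and MED23 at 13.8 ± 1.47 CPM in med23 ref4-3 (adjusted p = 7.20e-17). MED5B was at 20.3 ± 1.34 CPM in med5b-3 ref4-3, a log2 change of −0.24 ± 0.06 from WT (adjusted p = 0.00314), and at 22.8 ± 0.749 CPM in ref4-3. MED16 was at 18.8 ± 1.32 CPM in med16 ref4-3 and was not called against WT (adjusted p = 0.0899). The MED2 call in med2 ref4-3 was lost without any 1 of the 8 libraries compared, with log2 changes of −0.45 to −0.37. MED16 was called lower than WT without WT replicate 2 (log2 change −0.23).

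In mutant groups without a lesion in the gene, these 5 genes ran from 84.7% of the WT mean (MED2 in med5b-3 ref4-3) to 122% (MED16 in ref4-3). The labels of med2, med5ab, med16, med23 and med23 ref4-3 can be read from these levels. In the 5 lines that carry ref4-3, MED5B was at 80.2% (med23 ref4-3) to 94.4% (ref4-3). MED2 in med2 ref4-3 (74.9%) and MED16 in med16 ref4-3 (89.3%) had the lowest means of the 4 double mutants.

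**Figure D1:**
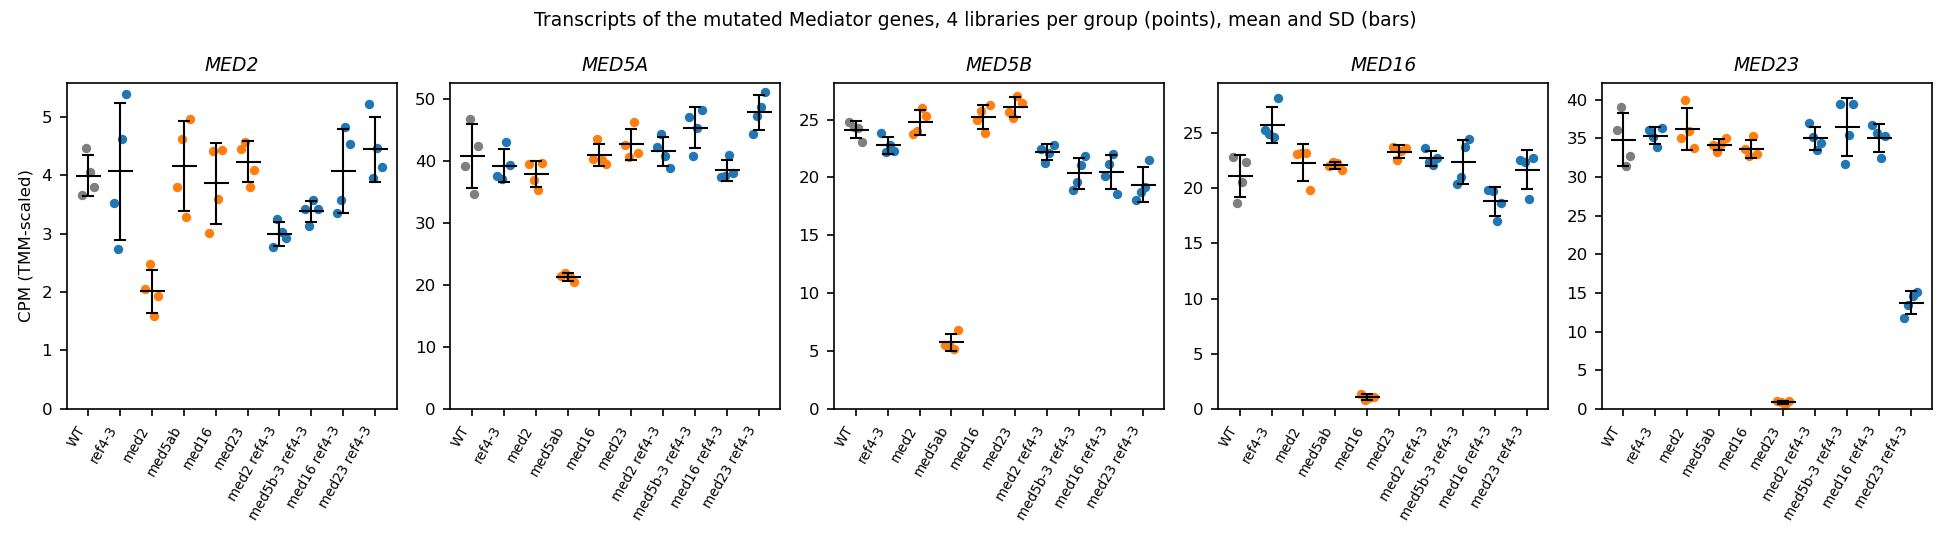
CPM of the 5 targeted Mediator genes in each of the 40 libraries, by group.

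In ref4-3, repressors of phenylpropanoid synthesis rose: KFB39 (165 ± 8.21 against 12.1 ± 1.99), MYB4 (51.5 ± 4.90 against 14.9 ± 1.75) and MYB7 (10.8 ± 0.475 against 1.83 ± 0.463) in CPM (highest adjusted p = 2.34e-15). Of the genes of lignin synthesis, some fell: CAD4 (59.5 ± 1.37 against 105 ± 8.99), HCT (105 ± 4.32 against 189 ± 6.74), PAL2 (116 ± 5.67 against 196 ± 14.8) and FAH1 (109.6 ± 10.1 against 161 ± 5.73) (highest adjusted p = 1.07e-10), while CAD5 (38.4 ± 8.03 against 23.1 ± 5.45) and CCR2 (2.02 ± 0.319 against 1.04 ± 0.228) rose (highest adjusted p = 0.0106). The CCR2 call was lost without WT replicate 4 (log2 change 0.84). The repressor KFB-CHS (58.5 ± 2.60 against 128 ± 6.39) fell as well (adjusted p = 4.21e-18). The sinapate glucosyltransferase genes UGT84A2 (115 ± 14.4 against 38.7 ± 2.40) and UGT84A3 (65.4 ± 5.04 against 35.6 ± 3.14) rose (highest adjusted p = 3.89e-11). Flavonoid genes rose: F3H (114 ± 16.2 against 32.7 ± 5.54), TT7 (49.0 ± 9.78 against 9.05 ± 3.02) and FLS1 (59.9 ± 3.73 against 35.8 ± 1.51) (highest adjusted p = 5.53e-12). Of 23 flavonoid genes, 19 rose, 0 fell and 4 were not called (adjusted over the list alone, 19 and 0; camera adjusted p = 1.34e-12, or adjusted p = 0.0419 if estimated). Of 9 repressor genes, 5 rose, 1 fell and 3 were not called (adjusted over the list alone, 5 and 1; camera adjusted p = 6.67e-04, or adjusted p = 0.0419 if estimated). Of 24 lignin and sinapate genes, 5 rose, 10 fell and 9 were not called (adjusted over the list alone, 5 and 10; camera adjusted p = 0.0617, or adjusted p = 0.425 if estimated). Of 18 secondary cell wall genes, 0 rose, 7 fell and 11 were not called (adjusted over the list alone, 0 and 7; camera adjusted p = 0.0617, or adjusted p = 0.425 if estimated). The secondary cell wall gene CESA4 (13.1 ± 1.62 against 21.0 ± 3.43) fell (adjusted p = 1.43e-04).

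**Figure D2:**
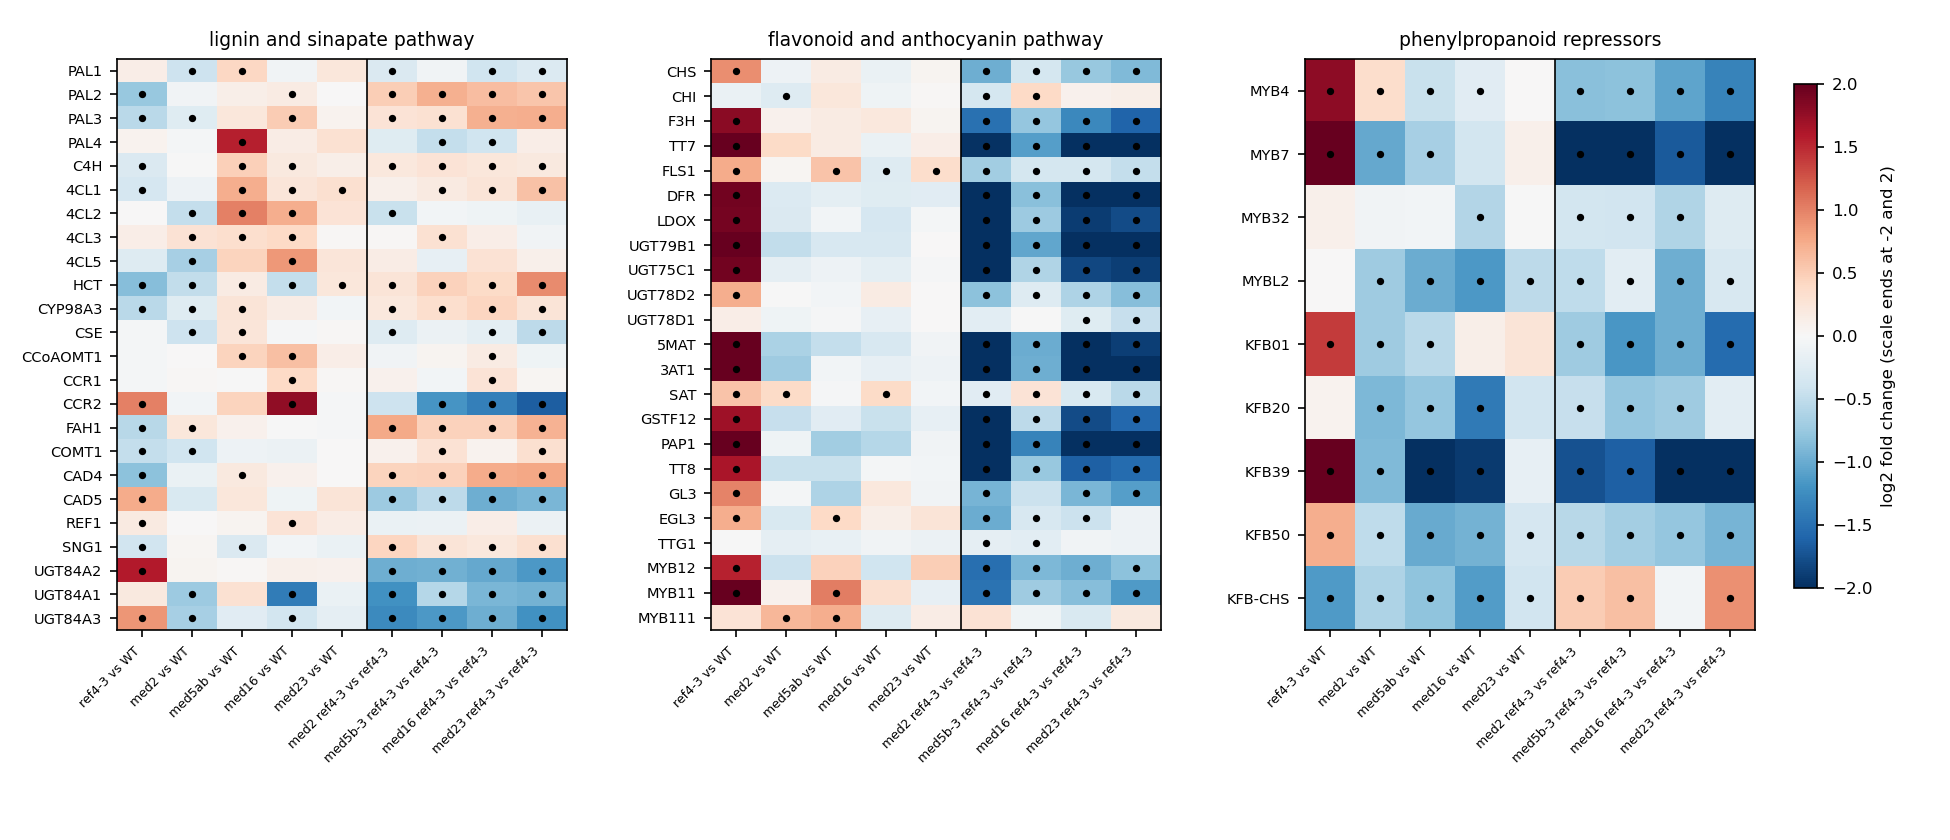
Log2 fold changes of lignin, sinapate, flavonoid and repressor genes in each comparison; dots mark edgeR quasi-likelihood, Benjamini-Hochberg adjusted p < 0.05, and the colour scale ends at −2 and 2.

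Defence genes rose in ref4-3: PR5 (117 ± 47.0 against 9.74 ± 2.63), DLO1 (6.23 ± 2.98 against 0.398 ± 0.428) and CBP60G (15.97 ± 4.97 against 5.23 ± 1.08) from salicylic acid defence and MYC2 (307 ± 46.1 against 117 ± 60.5) and JAZ10 (14.2 ± 3.75 against 5.24 ± 3.02) from jasmonate signalling (highest adjusted p = 1.19e-06). Of 25 salicylic acid defence genes, 23 rose, 0 fell and 2 were not called (adjusted over the list alone, 23 and 0; camera adjusted p = 2.60e-08, or adjusted p = 0.148 if estimated). Of 18 jasmonate and ethylene genes, 17 rose, 0 fell and 1 was not called (adjusted over the list alone, 17 and 0; camera adjusted p = 4.08e-06, or adjusted p = 0.148 if estimated). Cold-regulated genes rose, among them COR15A (377 ± 63.1 against 34.9 ± 6.54), COR15B (78.5 ± 8.80 against 11.02 ± 2) and KIN2 (234 ± 56.1 against 48.6 ± 19.3) (highest adjusted p = 1.48e-12), while CBF2 (0.726 ± 0.178 against 1.60 ± 0.793) fell (adjusted p = 0.00109). Of 15 cold genes, 10 rose, 1 fell and 4 were not called (adjusted over the list alone, 10 and 1; camera adjusted p = 1.06e-05, or adjusted p = 0.0709 if estimated). Of 12 clock genes, 10 rose, 1 fell and 1 was not called (adjusted over the list alone, 10 and 1; camera adjusted p = 6.67e-04, or adjusted p = 0.0419 if estimated).

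Auxin response genes fell in ref4-3, with IAA19 (1.35 ± 0.252 against 9.55 ± 0.444) and IAA6 (0.552 ± 0.0867 against 4.51 ± 0.462) (highest adjusted p = 6.19e-13), and so did photosynthesis genes, with RCA (7449 ± 537 against 12000 ± 399) and RBCS1B (893 ± 53.3 against 1784 ± 187) (highest adjusted p = 7.50e-13). Of 18 auxin response genes, 0 rose, 17 fell and 1 was not called (adjusted over the list alone, 0 and 17; camera adjusted p = 2.43e-09, or adjusted p = 0.0419 if estimated). Of 22 photosynthesis genes, 0 rose, 21 fell and 1 was not called (adjusted over the list alone, 0 and 22; camera adjusted p = 9.39e-14, or adjusted p = 0.0419 if estimated). Brassinosteroid genes PRE1 (10.2 ± 1.33 against 22.3 ± 2.71) and BES1 (70.2 ± 6.13 against 106 ± 5.10) fell (highest adjusted p = 4.05e-11) and ROT3 (10.6 ± 0.549 against 6.37 ± 0.701) rose (adjusted p = 1.68e-06). Of 16 brassinosteroid genes, 2 rose, 11 fell and 3 were not called (adjusted over the list alone, 2 and 11; camera adjusted p = 0.00162, or adjusted p = 0.0709 if estimated). The iron deficiency gene FRO3 (16.9 ± 1.44 against 27.8 ± 3.78) fell (adjusted p = 9.31e-09) and FRO2 (2.45 ± 0.391 against 1.51 ± 0.237) rose (adjusted p = 0.0107). Of 14 iron deficiency genes, 1 rose, 8 fell and 5 were not called (adjusted over the list alone, 1 and 9; camera adjusted p = 0.0166, or adjusted p = 0.350 if estimated).

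Of 12 xenobiotic genes, 6 rose, 0 fell and 6 were not called (adjusted over the list alone, 6 and 0; camera adjusted p = 0.00727, or adjusted p = 0.289 if estimated). The glucosinolate, flowering time, Mediator, heat shock and senescence lists did not pass camera (lowest adjusted p = 0.118, and lowest adjusted p = 0.355 if estimated).

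The root marker PYK10 (227 ± 35.7 against 91.9 ± 24.1) rose (adjusted p = 1.21e-07) and was the 1 root marker with enough counts to test (1 rose, 0 fell, adjusted over the list alone, 1 and 0), so camera was not run. The flower markers SEP2 (2.44 ± 0.895 against 0.822 ± 0.447) and AG (1.05 ± 0.433 against 2.38 ± 0.219) moved in opposite directions (highest adjusted p = 7.56e-04). Of 7 flower markers 4 rose and 1 fell (adjusted over the list alone, 4 and 1; camera adjusted p = 0.372, or adjusted p = 0.636 if estimated). Of 9 trichome and stomatal markers 4 rose and 1 fell (4 and 1; adjusted p = 0.194, or adjusted p = 0.355 if estimated). The seed marker list had 0 members with enough counts to test.

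By size of change, the increases were led by AT3G59930 (63.7 ± 10 against 0.940 ± 0.528), WAK3 (9.97 ± 3.03 against 0.344 ± 0.168) and ABCG40 (11.8 ± 6.74 against 0.558 ± 0.184), with AT5G35935 at 17.1 ± 1.3 CPM against 0.119 ± 0.104 and SBT3.3 at 11.5 ± 1.2 against 0.165 ± 0.209. The decreases were led by AT5G57760 (0.209 ± 0.109 against 7.32 ± 1.47), CER4 (0.311 ± 0.101 against 5.17 ± 1.67), ACS4 (0.769 ± 0.207 against 11.2 ± 1.71), CRK30 (0.321 ± 0.101 against 4.53 ± 0.425) and AT4G17860 (0.302 ± 0.134 against 3.95 ± 0.544) (highest adjusted p = 1.21e-08). In all, 9068 genes differed, 4633 higher and 4435 lower (51.1% higher, 70.3% with library size scaling, 48.5% with RLE). Under library size scaling the median log2 change of all genes was 0.13, against 0.02 with TMM.

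**Figure D3:**
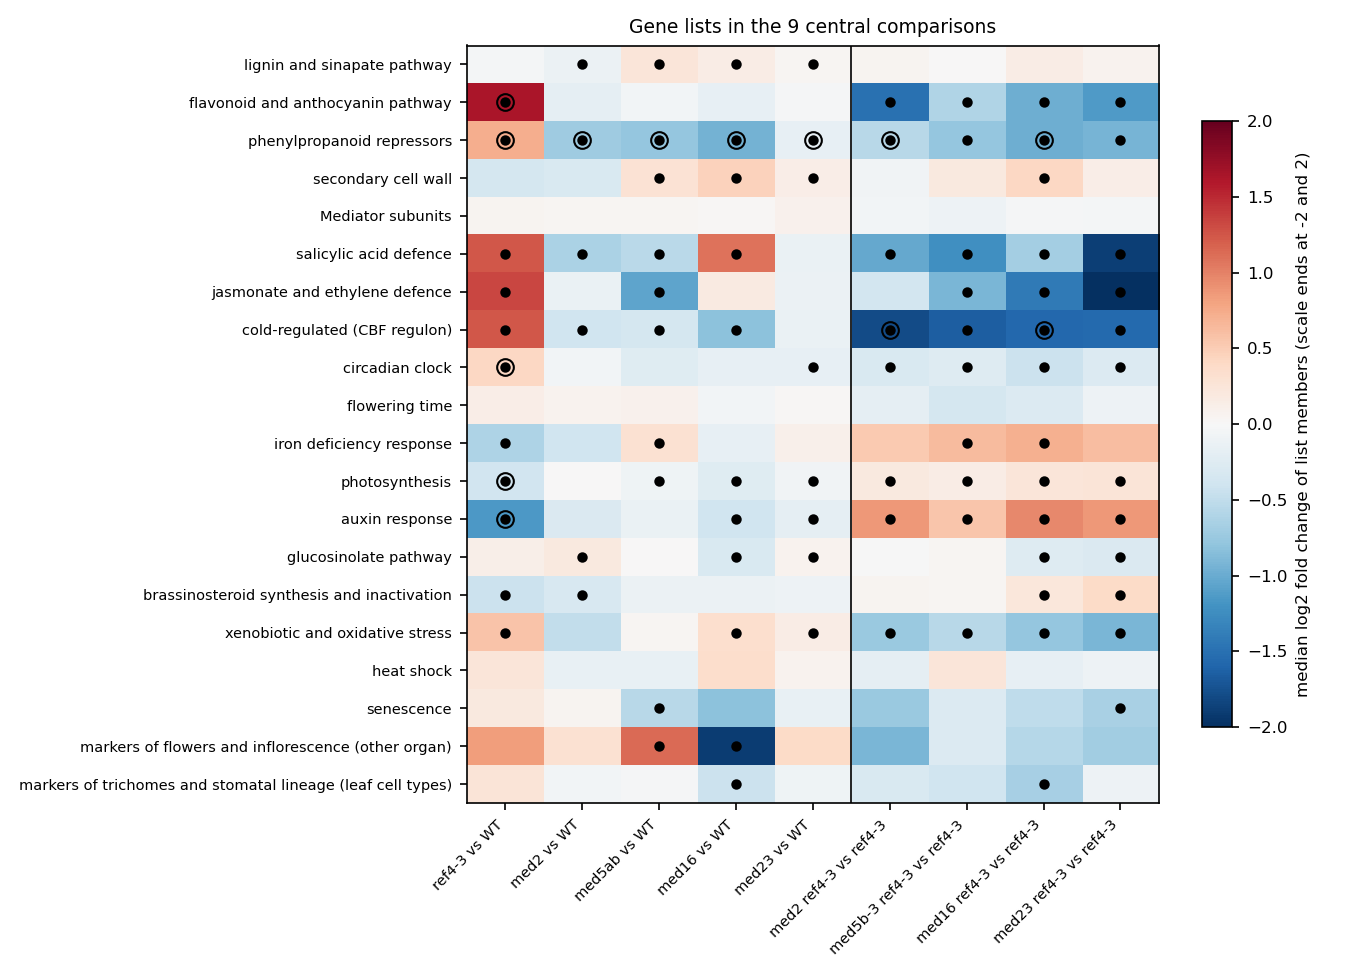
Median log2 fold change of each gene list in each comparison; dots mark camera adjusted p < 0.05 and rings mark adjusted p < 0.05 with an estimated correlation.

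In med2, MAF5 (4.22 ± 0.31), MAF4 (1.89 ± 0.24), FLC (1.87 ± 0.26) and SPL4 (1.21 ± 0.14) rose (highest adjusted p = 9.46e-07). Of 14 flowering time genes, 5 rose, 2 fell and 7 were not called (adjusted over the list alone, 5 and 3; camera adjusted p = 0.0651, or adjusted p = 0.522 if estimated). Repressors of phenylpropanoid synthesis fell, with MYBL2 (−0.71 ± 0.05), KFB-CHS (−0.61 ± 0.06) and KFB39 (−0.89 ± 0.11) (highest adjusted p = 1.96e-07), while MYB4 (0.35 ± 0.08) rose (adjusted p = 0.00150). Lignin and sinapate genes HCT (−0.49 ± 0.06), UGT84A3 (−0.67 ± 0.10) and COMT1 (−0.40 ± 0.06) fell and FAH1 (0.22 ± 0.06) rose (highest adjusted p = 0.00258). Cold genes COR414-TM1 (−1.70 ± 0.14) and GOLS3 (−1.82 ± 0.27), salicylic acid genes PBS3 (−1.09 ± 0.22) and EDS5 (−0.68 ± 0.15) and brassinosteroid genes BR6OX2 (−0.80 ± 0.09) and CPD (−0.41 ± 0.06) fell (highest adjusted p = 9.48e-04). Glucosinolate genes MAM3 (1.06 ± 0.13) and CYP79F2 (0.73 ± 0.13) rose (highest adjusted p = 5.34e-05), and the xylem gene XCP1 (−1.36 ± 0.22) fell (adjusted p = 8.23e-06).

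Repressor genes rose in 1, fell in 7 and were not called in 1 of 9 cases (adjusted over the list alone, 1 and 7; camera adjusted p = 1.97e-05, or adjusted p = 0.0198 if estimated). Lignin and sinapate genes rose in 2, fell in 10 and were not called in 12 of 24 cases (adjusted over the list alone, 2 and 10; camera adjusted p = 0.0101, or adjusted p = 0.522 if estimated). Cold genes rose in 0, fell in 9 and were not called in 6 of 15 cases (adjusted over the list alone, 0 and 9; camera adjusted p = 0.00102, or adjusted p = 0.405 if estimated). Among flower markers 0 of 7 rose and 1 fell (adjusted over the list alone, 0 and 0; camera adjusted p = 0.864, or adjusted p = 0.937 if estimated). Among trichome and stomatal markers 1 of 9 rose and 2 fell (2 and 2; adjusted p = 0.905, or adjusted p = 0.937 if estimated). The root marker fell (−0.59).

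The most increased genes in med2 were AT5G35935, at 17.1 ± 1.66 CPM against 0.119 ± 0.104, MAF5 (17.44 ± 1.04 against 0.933 ± 0.139), AT2G05914 (6.85 ± 2.60 against 0.819 ± 0.475), AT3G41979 (14.8 ± 2.28 against 2.94 ± 1.08) and AT2G43590 (13.5 ± 2.71 against 3.37 ± 0.916), and the most decreased were TH8 (0.246 ± 0.0957 against 2.33 ± 1.27), AT2G47880 (0.517 ± 0.233 against 3.92 ± 0.310), CML41 (0.537 ± 0.290 against 3.56 ± 0.903), CYP78A8 (1.70 ± 0.421 against 11.2 ± 1.42) and IAA29 (3.31 ± 1.27 against 15.2 ± 4.04) (highest adjusted p = 6.35e-04). In this comparison 5336 genes differed, 2562 higher and 2774 lower (48.0% higher, 37.5% with library size scaling).

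In med5ab, phenylpropanoid genes rose: PAL4 (1.55 ± 0.11), 4CL1 (0.73 ± 0.05), 4CL2 (1.002 ± 0.10) and C4H (0.48 ± 0.05) (highest adjusted p = 7.03e-09), while SNG1 (−0.30 ± 0.04) fell (adjusted p = 2.87e-06). The repressors fell, with MYBL2 (−0.99 ± 0.05), KFB39 (−2.15 ± 0.12), KFB50 (−1.001 ± 0.07) and KFB-CHS (−0.81 ± 0.06) (highest adjusted p = 5.60e-13). FLS1 (0.58 ± 0.07) rose (adjusted p = 4.12e-08). Jasmonate genes AOC2 (−1.07 ± 0.21), AOC1 (−1.31 ± 0.27) and JAZ1 (−1.37 ± 0.28), salicylic acid genes WRKY18 (−0.99 ± 0.16) and EDS5 (−0.86 ± 0.15), the cold gene COR414-TM1 (−0.63 ± 0.12) and senescence genes SEN1 (−1.75 ± 0.25) and SEN4 (−0.73 ± 0.11) fell (highest adjusted p = 5.78e-04). Iron deficiency genes BHLH39 (1.94 ± 0.37) and BHLH38 (1.51 ± 0.32) and flower markers AP1 (1.45 ± 0.27) and SEP3 (0.98 ± 0.21) rose (highest adjusted p = 9.71e-04).

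On the repressor list 0 genes rose, 8 fell and 1 of 9 were not called (adjusted over the list alone, 0 and 8; camera adjusted p = 2.78e-13, or adjusted p = 5.26e-05 if estimated). On the lignin and sinapate list 11 genes rose, 1 fell and 12 of 24 were not called (adjusted over the list alone, 13 and 2; camera adjusted p = 5.37e-08, or adjusted p = 0.0765 if estimated). Jasmonate and ethylene genes rose in 0, fell in 14 and were not called in 4 of 18 cases (adjusted over the list alone, 0 and 14; camera adjusted p = 2.63e-05, or adjusted p = 0.287 if estimated). 6 of 7 flower markers rose and 0 fell (adjusted over the list alone, 7 and 0; camera adjusted p = 1.32e-05, or adjusted p = 0.117 if estimated).

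AT5G35935 was at 15.1 ± 0.720 CPM against 0.119 ± 0.104 and led the increases in med5ab, with AT3G41979 (12.4 ± 1.5 against 2.94 ± 1.08), AT1G48750 (7.47 ± 1.47 against 1.79 ± 1.63) and MYB47 (2.21 ± 0.289 against 0.781 ± 0.290) and PAL4. The decreases were led by MRD1 (0.301 ± 0.126 against 25.4 ± 2.59), GRP9 (0.214 ± 0.0276 against 3.76 ± 1.07), BAM5 (30.9 ± 11.2 against 298 ± 268) and AT2G24210 (0.540 ± 0.156 against 5.01 ± 5.22), with AT3G59930 at 0.0771 ± 0.0622 CPM against 0.940 ± 0.528 (highest adjusted p = 0.00534). Between these groups 3753 genes differed, 1662 higher and 2091 lower (44.3% higher, 54.6% with library size scaling). The call of AT2G24210 was lost without WT replicate 3 (log2 change −2.08).

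Salicylic acid genes rose in med16, with WRKY38 (3.31 ± 0.40), GRX480 (2.77 ± 0.36) and WRKY70 (1.16 ± 0.15) (highest adjusted p = 1.28e-07). Genes of jasmonate and ethylene defence were divided: PR4 (−1.65 ± 0.24) fell, PDF1.2A had 0 counts in all 4 med16 libraries against 1.05 ± 0.568 CPM in WT, and JAZ10 (1.297 ± 0.23) rose (highest adjusted p = 8.83e-05). Cold genes COR414-TM1 (−2.83 ± 0.15), ERD10 (−0.97 ± 0.10) and LTI30 (−3.12 ± 0.35), photosynthesis genes LHCB5 (−0.41 ± 0.03) and RBCS2B (−0.78 ± 0.07) and glucosinolate genes CYP79F1 (−1.13 ± 0.10), BCAT4 (−1.22 ± 0.10) and MAM1 (−1.21 ± 0.11) fell (highest adjusted p = 3.21e-09). The repressors MYBL2 (−1.15 ± 0.05), KFB-CHS (−1.12 ± 0.06) and KFB39 (−1.91 ± 0.12) fell (highest adjusted p = 3.02e-15). Lignin genes CCoAOMT1 (0.60 ± 0.07) and CCR1 (0.40 ± 0.05) and xylem genes XCP2 (1.17 ± 0.17) and MYB85 (1.995 ± 0.30) rose, and HCT (−0.48 ± 0.06) and UGT84A1 (−1.40 ± 0.28) fell (highest adjusted p = 1.65e-04).

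In med16, SOC1 (−0.65 ± 0.06), FUL (−1.62 ± 0.22) and FT (−2.38 ± 0.39) fell and FLC (1.38 ± 0.26) rose (highest adjusted p = 8.19e-05). Flowering time genes rose in 2, fell in 4 and were not called in 8 of 14 cases (adjusted over the list alone, 2 and 5; camera adjusted p = 0.208, or adjusted p = 0.419 if estimated). Flower markers SEP1 (−2.31 ± 0.27) and AG (−2.39 ± 0.30), the stomatal lineage gene SPCH (−0.87 ± 0.13) and auxin genes GH3.6 (−1.02 ± 0.07) and IAA29 (−2.70 ± 0.25) fell (highest adjusted p = 1.48e-06). Of the clock genes, LHY (0.76 ± 0.06) rose and PRR5 (−1.73 ± 0.19) fell (highest adjusted p = 3.77e-09). Salicylic acid defence genes rose in 16, fell in 0 and were not called in 9 of 25 cases (adjusted over the list alone, 18 and 0; camera adjusted p = 1.71e-07, or adjusted p = 0.211 if estimated). On the cold list 1 gene rose, 10 fell and 4 of 15 were not called (adjusted over the list alone, 1 and 10; camera adjusted p = 2.02e-05, or adjusted p = 0.120 if estimated). Among 9 repressor genes, 0 rose, 7 fell and 2 were not called (adjusted over the list alone, 0 and 7; camera adjusted p = 1.11e-09, or adjusted p = 7.59e-04 if estimated). Among 24 lignin and sinapate genes, 11 rose, 3 fell and 10 were not called (adjusted over the list alone, 11 and 3; camera adjusted p = 0.00896, or adjusted p = 0.329 if estimated). For flower markers, 0 of 7 rose and 6 fell (adjusted over the list alone, 0 and 6; camera adjusted p = 3.82e-04, or adjusted p = 0.190 if estimated). 0 of 9 trichome and stomatal markers rose and 4 fell (0 and 5; adjusted p = 0.0107, or adjusted p = 0.120 if estimated).

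The most increased genes in med16 were AT5G35935, at 17.39 ± 0.530 CPM against 0.119 ± 0.104, and TAT3 (223 ± 63.1 against 12.6 ± 5.74), ABCG40 (8.22 ± 6.85 against 0.558 ± 0.184), BSMT1 (34.0 ± 11 against 3.10 ± 3.06) and MDHAR (14.0 ± 5.44 against 1.32 ± 1.16). The most decreased were MRD1 (0.456 ± 0.169 against 25.4 ± 2.59), AT2G20870 (0.291 ± 0.213 against 9.95 ± 3.81), FH3 (0.355 ± 0.163 against 10.1 ± 10.7) and BAM5 (12.1 ± 3.47 against 298 ± 268) and EXLB1, at 0.0165 ± 0.0330 CPM against 3.91 ± 0.753 (highest adjusted p = 4.32e-06). In all, 5628 genes differed, 2806 higher and 2822 lower (49.9% higher, 59.0% with library size scaling).

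Of these 5 mutants, med23 had the fewest changed genes. The repressors MYBL2 (54.2 ± 1.90 against 77.5 ± 5.83), KFB-CHS (98.7 ± 2.52 against 128 ± 6.39) and KFB50 (89.2 ± 5.49 against 112 ± 8.87) fell (highest adjusted p = 0.00313), and 4CL1 (135 ± 8.36 against 109 ± 7.83) and FLS1 (45.6 ± 4.39 against 35.8 ± 1.51) rose (highest adjusted p = 0.00211). MAM3 (21.2 ± 2.42 against 12.9 ± 2.23) rose, and PRR5 (3.69 ± 0.538 against 6.57 ± 0.626) and WRKY53 (1.88 ± 0.568 against 4.94 ± 1.51) fell (highest adjusted p = 0.00684). The increases were led by AT5G35935, at 16.98 ± 1.40 CPM against 0.119 ± 0.104, and AT3G30122 (7.37 ± 0.825 against 2.44 ± 0.925), AT2G01008 (2.89 ± 0.224 against 0.992 ± 0.257), AT3G44970 (13.2 ± 1.31 against 5.596 ± 1.62) and AG (4.78 ± 1.08 against 2.38 ± 0.219). The decreases were led by MED23 and DIC2 (2.21 ± 0.262 against 9.31 ± 3.35), CAF1a (3.92 ± 0.32 against 13.3 ± 5.07), ERF104 (1.55 ± 0.152 against 4.91 ± 1.51) and AT1G07135 (1.22 ± 0.259 against 3.75 ± 2.27) (highest adjusted p = 0.00933). Of 9 repressor genes, 0 rose, 3 fell and 6 were not called (adjusted over the list alone, 0 and 4; camera adjusted p = 1.38e-04, or adjusted p = 0.0428 if estimated). Of 24 lignin and sinapate genes, 2 rose, 0 fell and 22 were not called (adjusted over the list alone, 3 and 1; camera adjusted p = 0.00604, or adjusted p = 0.491 if estimated). Of 7 flower markers 1 rose and 0 fell (adjusted over the list alone, 1 and 0; camera adjusted p = 0.0767, or adjusted p = 0.566 if estimated).

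In this comparison 377 genes differed, 118 higher and 259 lower. A fit of only these 2 groups gave 204 genes. The count of genes changed in med23 was 239 without med23 replicate 3. The call of AG was lost without med23 replicate 1 (log2 change 0.86) and that of AT1G07135 without WT replicate 3 (log2 change −1.16).

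KFB39 rose in ref4-3 and fell in med2, med5ab and med16, and MYBL2 fell in med2, med5ab, med16 and med23. Genes that moved the same way and in opposite ways, with the counts expected from unrelated calls in parentheses, numbered 1342 and 1833 (1240.2 and 1242) for ref4-3 and med2, 1006 and 1417 (871 and 875) for ref4-3 and med5ab, 2015 and 1396 (1309 and 1309) for ref4-3 and med16 and 162 and 95 (87.0 and 88.4) for ref4-3 and med23. They were 1778 and 168 (516 and 511) for med2 and med5ab, 2502 and 249 (771 and 770.3) for med2 and med16 and 204 and 30 (52.4 and 50.8) for med2 and med23. The last were 1608 and 350 (542 and 542) for med5ab and med16, 313 and 1 (37.8 and 34.7) for med5ab and med23 and 270 and 27 (54.5 and 54.4) for med16 and med23.

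Because all 10 pairs share the WT libraries, simulated mutants without any effect already had a correlation of 0.467 to 0.513 (highest of 20 draws per pair 0.553). The observed correlation across genes, and then that with the WT libraries split 2 and 2 so that none was shared, was −0.0347 and −0.0855 for ref4-3 and med2, −0.0898 and −0.128 for ref4-3 and med5ab, 0.243 and 0.183 for ref4-3 and med16, 0.153 and 0.0520 for ref4-3 and med23 and 0.437 and 0.248 for med2 and med5ab. For the rest these were 0.365 and 0.233 for med2 and med16, 0.279 and 0.0474 for med2 and med23, 0.132 and 0.0264 for med5ab and med16, 0.522 and 0.236 for med5ab and med23 and 0.301 and 0.115 for med16 and med23, and genes are not independent replicates. In the same order of pairs the covariance was −0.00925, −0.0219, 0.0816, 0.0245, 0.0713, 0.0817, 0.0299, 0.0272, 0.0512 and 0.0405, against 0.0189 to 0.0191 simulated without any effect. The count shared by med2 and med23 was 134 without med23 replicate 1 and 130 without med23 replicate 3, and that shared by med5ab and med23 was 205 without med23 replicate 3. Genes in opposite ways were counted too. For ref4-3 and med23 they numbered 58 without WT replicate 1, 61 without WT replicate 2, 56 without med23 replicate 1 and 53 without med23 replicate 3. For med2 and med23 they numbered 16 without WT replicate 1, 19 without WT replicate 2 and 17 without med23 replicate 3. For med5ab and med23 they numbered 0 without WT replicate 2, 2 without WT replicate 3 and 0 without med23 replicate 4. For med16 and med23 they numbered 16 without WT replicate 1 and 14 without med23 replicate 3.

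The 4 lines with a second lesion were compared with ref4-3. The same 4 ref4-3 libraries stand on both sides of a return towards WT, so simulated lines were run as a scale: with full return, 84.7 to 86.8% of the genes changed in ref4-3 were called back, and with no return 0 to 0.00108%. The median share of the change left was 0.0344 to 0.0351 and 0.965 to 0.966.

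Adding the med2 lesion to ref4-3 lowered flavonoid genes, with F3H (−1.49 ± 0.11) and UGT79B1 (−2.99 ± 0.25) (highest adjusted p = 7.08e-13), and the repressors KFB39 (−1.75 ± 0.07) and MYB7 (−2.001 ± 0.16) (highest adjusted p = 2.11e-13). FAH1 (0.76 ± 0.06) and SNG1 (0.44 ± 0.04) rose and UGT84A3 (−1.28 ± 0.09) and UGT84A2 (−0.98 ± 0.08) fell (highest adjusted p = 3.86e-11). Cold genes COR15A (−4.08 ± 0.18), COR15B (−3.53 ± 0.20) and RD29A (−1.80 ± 0.12) and salicylic acid genes PBS3 (−1.36 ± 0.17) and WRKY70 (−1.18 ± 0.15) fell (highest adjusted p = 2.30e-08). The photosynthesis gene RCA (0.53 ± 0.04) and the auxin gene IAA6 (2.48 ± 0.25) rose (highest adjusted p = 1.44e-10). Flavonoid genes rose in 0, fell in 21 and were not called in 2 of 23 cases (adjusted over the list alone, 0 and 22; camera adjusted p = 1.93e-11, or adjusted p = 0.0674 if estimated). Repressor genes rose in 1, fell in 8 and were not called in 0 of 9 cases (adjusted over the list alone, 1 and 8; camera adjusted p = 9.03e-05, or adjusted p = 0.0396 if estimated). Among 15 cold genes, 0 rose, 14 fell and 1 was not called (adjusted over the list alone, 0 and 15; camera adjusted p = 1.61e-10, or adjusted p = 0.0315 if estimated). Among flower markers 0 of 7 rose and 6 fell (adjusted over the list alone, 0 and 6; camera adjusted p = 0.0980, or adjusted p = 0.628 if estimated). For trichome and stomatal markers, 2 of 9 rose and 5 fell (2 and 5; adjusted p = 0.400, or adjusted p = 0.628 if estimated). The root marker fell (−0.86).

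The largest decreases in med2 ref4-3 were AT3G53980 (0.513 ± 0.0910 against 9.69 ± 1.79), PUB19 (0.822 ± 0.170 against 9.59 ± 3.54) and TH8 (0.784 ± 0.433 against 7.08 ± 0.759), with COR15A and COR15B (highest adjusted p = 2.89e-10). The largest increases were chloroplast genes, ATCG00270 (190.0 ± 361 against 5.87 ± 1.28), ATCG00020 (1059 ± 1940 against 39.5 ± 7.05), ATCG00100 (15.5 ± 28.3 against 0.701 ± 0.340), ATCG00690 (19.7 ± 35.8 against 1.04 ± 0.275) and ATCG00680 (169 ± 304 against 10.2 ± 1.49) (highest adjusted p = 1.13e-05), and their size rests on med2 ref4-3 replicate 1. Without that library they were still called, at log2 changes of ATCG00270 (0.74), ATCG00020 (1.22), ATCG00100 (1.01), ATCG00690 (0.78) and ATCG00680 (0.70). MED2 was at 2.99 ± 0.2 CPM against 4.06 ± 1.18 in ref4-3 (adjusted p = 0.0131). This call was lost without ref4-3 replicate 4 (log2 change −0.28). Between these groups 9677 genes differed, 4450 higher and 5227 lower (46.0% higher, 30.1% with library size scaling). Of the genes changed in ref4-3, 6423 (70.8%) were called back towards WT and 151 further away (64.0% back with the ref4-3 libraries divided 2 and 2). The median share of the ref4-3 change left was 0.16. Of these genes 2295 differed from WT in the ref4-3 direction and 1047 in the other.

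In med5b-3 ref4-3, lignin genes PAL2 (0.71 ± 0.05) and CAD4 (0.46 ± 0.06) rose and UGT84A3 (−1.15 ± 0.09) and UGT84A2 (−0.97 ± 0.08) fell relative to ref4-3 (highest adjusted p = 7.10e-09). Flavonoid genes F3H (−0.78 ± 0.10) and TT7 (−1.10 ± 0.17) fell, while CHI (0.40 ± 0.09) rose (highest adjusted p = 1.72e-04). The repressors KFB39 (−1.64 ± 0.07) and MYB7 (−2.14 ± 0.17), defence genes PR5 (−2.24 ± 0.25), WRKY70 (−1.29 ± 0.15), OPR3 (−1.08 ± 0.20) and PR4 (−1.11 ± 0.21) and cold genes COR15A (−2.74 ± 0.16) and COR15B (−3.24 ± 0.20) fell (highest adjusted p = 2.31e-05). Iron genes FRO3 (0.65 ± 0.09) and OPT3 (0.62 ± 0.09), the photosynthesis gene RCA (0.70 ± 0.04) and the auxin gene IAA19 (2.005 ± 0.20) rose (highest adjusted p = 1.89e-07). On the flavonoid list 2 genes rose, 18 fell and 3 of 23 were not called (adjusted over the list alone, 2 and 19; camera adjusted p = 6.52e-04, or adjusted p = 0.367 if estimated). On the repressor list 1 gene rose, 8 fell and 0 of 9 were not called (adjusted over the list alone, 1 and 8; camera adjusted p = 1.50e-04, or adjusted p = 0.0803 if estimated). 0 of 7 flower markers rose and 2 fell (adjusted over the list alone, 0 and 2; camera adjusted p = 0.381, or adjusted p = 0.640 if estimated). Of 9 trichome and stomatal markers 0 rose and 4 fell (0 and 4; adjusted p = 0.185, or adjusted p = 0.367 if estimated). The root marker fell (−0.76).

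The largest increases in med5b-3 ref4-3 were AT5G57760 (4.11 ± 0.844 against 0.209 ± 0.109), FLA9 (63.6 ± 6.17 against 5.25 ± 0.440), AT1G50040 (3.31 ± 0.783 against 0.309 ± 0.224), ACS4 (8.13 ± 1.67 against 0.769 ± 0.207) and AT5G62730 (3.76 ± 0.310 against 0.311 ± 0.232). The largest decreases were AT5G35935, at 0.0546 ± 0.0679 CPM against 17.1 ± 1.3, and MRD1 (0.375 ± 0.123 against 21.7 ± 1.47), CML41 (1.60 ± 0.423 against 20.2 ± 7.54) and GolS2 (1.08 ± 0.494 against 11.1 ± 5.47), with COR15B (highest adjusted p = 3.34e-10). MED5B was at 20.3 ± 1.34 CPM against 22.8 ± 0.749 (adjusted p = 0.0299). This call was lost without ref4-3 replicate 1 (log2 change −0.14), without ref4-3 replicate 3 (log2 change −0.15), without med5b-3 ref4-3 replicate 1 (log2 change −0.12) and without med5b-3 ref4-3 replicate 2 (log2 change −0.14). In all, 9805 genes differed, 4620 higher and 5185 lower (47.1% higher, 33.4% with library size scaling). Of the genes changed in ref4-3, 6761 (74.6%) were called back towards WT and 85 further away (67.3% back with the ref4-3 libraries divided 2 and 2). The median share of the ref4-3 change left was 0.11. Of these genes 1659 differed from WT in the ref4-3 direction and 1048 in the other.

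Relative to ref4-3, med16 ref4-3 had higher levels of CAD4 (0.75 ± 0.06) and PAL2 (0.62 ± 0.05) and lower levels of UGT84A2 (−1.02 ± 0.08) and UGT84A3 (−0.97 ± 0.09), of flavonoid genes F3H (−1.29 ± 0.11) and TT7 (−2.04 ± 0.19) and of the repressors KFB39 (−2.08 ± 0.08) and MYBL2 (−0.97 ± 0.05) (highest adjusted p = 2.43e-11). Defence genes CBP60G (−2.14 ± 0.23), WRKY18 (−1.36 ± 0.15), OPR3 (−1.67 ± 0.21) and VSP1 (−3.26 ± 0.46) and cold genes COR15A (−3.25 ± 0.17) and KIN2 (−3.08 ± 0.21) fell (highest adjusted p = 2.13e-07). RCA (0.55 ± 0.04) of photosynthesis and IAA19 (1.93 ± 0.20) of auxin response rose (highest adjusted p = 4.70e-10). Among 23 flavonoid genes, 0 rose, 20 fell and 3 were not called (adjusted over the list alone, 0 and 20; camera adjusted p = 6.76e-10, or adjusted p = 0.0681 if estimated). Among 9 repressor genes, 0 rose, 8 fell and 1 was not called (adjusted over the list alone, 0 and 8; camera adjusted p = 2.53e-08, or adjusted p = 0.00246 if estimated). For flower markers, 0 of 7 rose and 4 fell (adjusted over the list alone, 0 and 4; camera adjusted p = 0.204, or adjusted p = 0.4998 if estimated). Among trichome and stomatal markers 1 of 9 rose and 7 fell (1 and 8; adjusted p = 0.00486, or adjusted p = 0.0681 if estimated). The root marker fell (−1.11).

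The largest increases in med16 ref4-3 were AT5G57760 (2.96 ± 0.438 against 0.209 ± 0.109), AT2G05914 (4.05 ± 0.684 against 0.446 ± 0.118), FLA9 (47.0 ± 7.19 against 5.25 ± 0.440), AT5G62730 (3.02 ± 0.475 against 0.311 ± 0.232) and AT4G17860 (2.63 ± 0.548 against 0.302 ± 0.134). The largest decreases were AT5G35935, at 0.161 ± 0.0622 CPM against 17.1 ± 1.3, and FH3 (1.94 ± 0.947 against 29.9 ± 6.33), AT3G53980 (0.626 ± 0.253 against 9.69 ± 1.79), CYP94B3 (0.785 ± 0.448 against 10.9 ± 7.19) and AT4G02360 (1.07 ± 0.186 against 15.2 ± 6.38) (highest adjusted p = 3.57e-05). MED16 was lower than in ref4-3, by −0.47 ± 0.07 (adjusted p = 9.01e-07). In this comparison 8964 genes differed, 4350 higher and 4614 lower (48.5% higher, 36.4% with library size scaling, 51.3% with RLE). Of the genes changed in ref4-3, 6636 (73.2%) were called back towards WT and 69 further away (65.2% back with the ref4-3 libraries divided 2 and 2). The median share of the ref4-3 change left was 0.14. Of these genes 1382 differed from WT in the ref4-3 direction and 388 in the other.

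In med23 ref4-3, lignin genes HCT (0.94 ± 0.06) and CAD4 (0.77 ± 0.06) rose and UGT84A2 (−1.14 ± 0.08) and UGT84A3 (−1.21 ± 0.09) fell (highest adjusted p = 1.17e-14), as did flavonoid genes F3H (−1.60 ± 0.11) and TT7 (−2.37 ± 0.19) and the repressors KFB39 (−2.51 ± 0.08) and MYB4 (−1.33 ± 0.07) (highest adjusted p = 2.60e-13). Defence genes WRKY70 (−1.89 ± 0.16), CBP60G (−2.57 ± 0.23), MYC2 (−2.25 ± 0.22) and OPR3 (−2.10 ± 0.21) fell (highest adjusted p = 5.57e-11). Cold genes COR15A (−2.55 ± 0.16) and RD29A (−1.66 ± 0.12) fell, while GOLS3 (0.74 ± 0.20) rose (highest adjusted p = 0.00205). RCA (0.48 ± 0.04) of photosynthesis and IAA19 (2.67 ± 0.19) of auxin response rose (highest adjusted p = 3.56e-12). Of 23 flavonoid genes, 0 rose, 19 fell and 4 were not called (adjusted over the list alone, 0 and 19; camera adjusted p = 2.68e-09, or adjusted p = 0.121 if estimated). Of 9 repressor genes, 1 rose, 6 fell and 2 were not called (adjusted over the list alone, 1 and 6; camera adjusted p = 1.52e-04, or adjusted p = 0.106 if estimated). Of 7 flower markers 1 rose and 4 fell (adjusted over the list alone, 1 and 4; camera adjusted p = 0.393, or adjusted p = 0.647 if estimated). 0 of 9 trichome and stomatal markers rose and 2 fell (0 and 2; adjusted p = 0.335, or adjusted p = 0.509 if estimated). The root marker fell (−0.65).

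The largest increases in med23 ref4-3 were AT5G57760 (6.86 ± 1.73 against 0.209 ± 0.109), AT1G50040 (4.34 ± 1.09 against 0.309 ± 0.224), CRK30 (4.14 ± 1.48 against 0.321 ± 0.101), FLA9 (65.2 ± 23.7 against 5.25 ± 0.440) and ACS4 (7.83 ± 2 against 0.769 ± 0.207), and the largest decreases MRD1 (0.473 ± 0.108 against 21.7 ± 1.47), RLP40 (0.723 ± 0.461 against 29.0 ± 3.85), AT2G24210 (0.703 ± 0.480 against 29.4 ± 16.7), CYP82G1 (0.237 ± 0.175 against 7.91 ± 0.967) and PR2 (2.82 ± 1.05 against 92.6 ± 40.8) (highest adjusted p = 4.27e-09). MED23 was lower than in ref4-3, by −1.37 ± 0.07 (adjusted p = 1.63e-18). Between these groups 10167 genes differed, 4923 higher and 5244 lower (48.4% higher, 34.7% with library size scaling, 50.1% with RLE). Of the genes changed in ref4-3, 7219 (79.6%) were called back towards WT and 47 further away (73.7% back with the ref4-3 libraries divided 2 and 2). The median share of the ref4-3 change left was −0.01. Of these genes 970 differed from WT in the ref4-3 direction and 1105 in the other.

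Against WT, med2 ref4-3 still had more KFB39 (2.02 ± 0.09), MYB4 (0.95 ± 0.08) and UGT84A2 (0.60 ± 0.08) and less HCT (−0.60 ± 0.06) (highest adjusted p = 4.85e-07). Defence genes PR5 (2.26 ± 0.28) and WRKY38 (2.60 ± 0.42) and FLC (1.74 ± 0.25) rose, and IAA29 (−3.02 ± 0.25), COR414-TM1 (−1.88 ± 0.14), LHCA1 (−0.38 ± 0.04) and BR6OX2 (−0.70 ± 0.09) fell (highest adjusted p = 1.01e-05). The largest increases were AT5G35935, at 17.65 ± 0.544 CPM against 0.119 ± 0.104, and the chloroplast genes ATCG00350 (5.34 ± 0.88) and ATCG00560 (5.28 ± 0.94), and the largest decreases IAA29 and AT2G47880 (−2.35 ± 0.28) and DIC2 (−2.32 ± 0.25) (highest adjusted p = 4.12e-05). Of 15 cold genes, 0 rose, 10 fell and 5 were not called (adjusted over the list alone, 0 and 12; camera adjusted p = 2.27e-05, or adjusted p = 0.202 if estimated). Among flower markers 0 of 7 rose and 3 fell (adjusted over the list alone, 0 and 3; camera adjusted p = 0.194, or adjusted p = 0.690 if estimated). For trichome and stomatal markers, 0 of 9 rose and 1 fell (0 and 1; adjusted p = 0.823, or adjusted p = 0.905 if estimated). In all, 5511 genes differed, 2619 higher and 2892 lower (47.5% higher, 51.8% with library size scaling). Without med2 ref4-3 replicate 1 the log2 changes were ATCG00350 (0.83) and ATCG00560 (1.39), and the second call was lost.

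In med5b-3 ref4-3, KFB39 (2.13 ± 0.09), MYB4 (0.96 ± 0.08), UGT84A2 (0.61 ± 0.08) and SAT (0.85 ± 0.08) were above WT and HCT (−0.40 ± 0.06) below it (highest adjusted p = 1.73e-06). Flavonoid genes F3H (1.02 ± 0.11) and TT7 (1.39 ± 0.20) were higher, and IAA29 (−2.29 ± 0.24), LHCA1 (−0.37 ± 0.04) and BR6OX2 (−0.84 ± 0.09) lower (highest adjusted p = 2.85e-06). By size, the changes were led by AT3G59930 (4.91 ± 0.24) and AT5G47600 (3.67 ± 0.21), SBT3.3 at 1.49 ± 0.271 CPM against 0.165 ± 0.209, MRD1 (−6.07 ± 0.22) and SEN1 (−2.04 ± 0.26) and IAA29 (highest adjusted p = 2.69e-05). Flavonoid genes rose in 18, fell in 1 and were not called in 4 of 23 cases (adjusted over the list alone, 20 and 1; camera adjusted p = 2.70e-14, or adjusted p = 0.0563 if estimated). 0 of 7 flower markers rose and 1 fell (adjusted over the list alone, 0 and 1; camera adjusted p = 0.965, or adjusted p = 0.982 if estimated). Of 9 trichome and stomatal markers 0 rose and 1 fell (0 and 0; adjusted p = 0.860, or adjusted p = 0.982 if estimated). The root marker rose (0.54). In this comparison 4282 genes differed, 2235 higher and 2047 lower.

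Against WT, med16 ref4-3 had more KFB39 (1.69 ± 0.09), UGT84A2 (0.56 ± 0.08), FLS1 (0.39 ± 0.07) and PR5 (1.44 ± 0.30) and less KFB-CHS (−1.18 ± 0.06), HCT (−0.46 ± 0.06), COR414-TM1 (−1.64 ± 0.14) and LHCB5 (−0.29 ± 0.03) (highest adjusted p = 7.14e-04). The largest changes were GRP9 (3.45 ± 0.39) and AT3G59930 (2.79 ± 0.31), SBT3.3 at 1.60 ± 0.724 CPM against 0.165 ± 0.209, and AT2G47880 (−2.89 ± 0.32), AT4G01390 (−2.47 ± 0.25) and DIC2 (−2.45 ± 0.27) (highest adjusted p = 5.21e-05). Photosynthesis genes rose in 0, fell in 12 and were not called in 10 of 22 cases (adjusted over the list alone, 0 and 14; camera adjusted p = 8.89e-13, or adjusted p = 0.127 if estimated). For flower markers, 0 of 7 rose and 1 fell (adjusted over the list alone, 0 and 1; camera adjusted p = 0.662, or adjusted p = 0.878 if estimated). Among trichome and stomatal markers 0 of 9 rose and 2 fell (0 and 3; adjusted p = 0.00986, or adjusted p = 0.127 if estimated). Between these groups 2710 genes differed, 1240 higher and 1470 lower (45.8% higher, 65.0% with library size scaling).

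In med23 ref4-3, KFB39 (1.26 ± 0.09), MYB4 (0.45 ± 0.08) and UGT84A2 (0.44 ± 0.08) were above WT and CSE (−0.56 ± 0.07) below it (highest adjusted p = 2.14e-04). WRKY18 (−0.81 ± 0.16), RCA (−0.20 ± 0.04) and WRKY53 (−2.85 ± 0.30) fell and COR15B (1.23 ± 0.20) rose (highest adjusted p = 8.77e-04). The changes were led by AT5G35935, at 11.2 ± 1.19 CPM against 0.119 ± 0.104, AT3G59930 (2.84 ± 0.29) and AT3G05727 (2.28 ± 0.29) and MRD1 (−5.72 ± 0.21), BAM5 (−3.37 ± 0.43) and STZ (−3.14 ± 0.36) (highest adjusted p = 6.48e-07). Of 7 flower markers 0 rose and 1 fell (adjusted over the list alone, 0 and 1; camera adjusted p = 0.978, or adjusted p = 0.984 if estimated). 0 of 9 trichome and stomatal markers rose and 1 fell (0 and 1; adjusted p = 0.617, or adjusted p = 0.751 if estimated). The root marker rose (0.65). In all, 3421 genes differed, 1619 higher and 1802 lower (47.3% higher, 56.9% with library size scaling). A fit of only these 2 groups gave 1478 genes. The median, mean and camera direction of flower markers differ in sign in med2, med5b-3 ref4-3 and med23 ref4-3 against WT, as do those of trichome and stomatal markers in med5b-3 ref4-3.

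Compared with med2, med2 ref4-3 had more KFB39 (2.91 ± 0.10) and PR5 (2.39 ± 0.30) (highest adjusted p = 6.45e-07). Its largest changes were AT3G59930 (4.46 ± 0.23), ATCG00270 (5.05 ± 0.89) and ATCG00520 (4.87 ± 0.89) and MAF5 (−3.25 ± 0.28), DIC2 (−2.86 ± 0.24) and AT2G05914 (−2.42 ± 0.24) (highest adjusted p = 2.86e-04). The root marker rose (1.04). In this comparison 1712 genes differed, 1028 higher and 684 lower (60.05% higher, 78.9% with library size scaling). The count was 1124 without med2 ref4-3 replicate 4, and without med2 ref4-3 replicate 1 the log2 changes of the chloroplast genes were ATCG00270 (0.76) and ATCG00520 (0.87), the second no longer called. Without med2 replicate 2 as well, the call of ATCG00270 ended (log2 change 0.76).

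Compared with med5ab, med5b-3 ref4-3 had more KFB39 (4.28 ± 0.11) and less PAL4 (−1.96 ± 0.12) and 4CL1 (−0.89 ± 0.05) (highest adjusted p = 7.70e-16). The largest changes were AT3G59930, at 27.2 ± 2.04 CPM against 0.0771 ± 0.0622, GRP9 (6.23 ± 0.65) and FH3 (5.20 ± 0.55), AT5G35935, at 0.0546 ± 0.0679 CPM against 15.1 ± 0.720, and PCC1 (−2.13 ± 0.36) and GolS2 (−2.08 ± 0.33) (highest adjusted p = 1.77e-05). Among flower markers 0 of 7 rose and 6 fell (adjusted over the list alone, 0 and 6; camera adjusted p = 3.04e-04, or adjusted p = 0.129 if estimated). The root marker rose (0.84). Between these groups 5743 genes differed, 3128 higher and 2615 lower.

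Compared with med16, med16 ref4-3 had more MED16 (4.15 ± 0.12) and KFB39 (3.598 ± 0.11) (highest adjusted p = 9.69e-26). The largest changes were GRP9 (7.83 ± 0.63) and MRD1 (5.53 ± 0.22), EXLB1, at 2.11 ± 0.382 CPM against 0.0165 ± 0.0330, AT5G35935, at 0.161 ± 0.0622 CPM against 17.39 ± 0.530, and LAS1 (−2.63 ± 0.30) and BSMT1 (−2.58 ± 0.47) (highest adjusted p = 1.73e-04). 6 of 7 flower markers rose and 0 fell (adjusted over the list alone, 7 and 0; camera adjusted p = 1.15e-06, or adjusted p = 0.0701 if estimated). In all, 2079 genes differed, 1060 higher and 1019 lower.

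Compared with med23, med23 ref4-3 had more MED23 (3.93 ± 0.14) and KFB39 (1.43 ± 0.09) (highest adjusted p = 4.87e-14). The largest changes were AT3G59930 (3.15 ± 0.32) and AT4G22513 (2.67 ± 0.44), MED23 and MRD1 (−4.30 ± 0.24), AT2G24210 (−3.15 ± 0.76) and TPS04 (−2.26 ± 0.47) (highest adjusted p = 0.00576). For trichome and stomatal markers, 1 of 9 rose and 0 fell (adjusted over the list alone, 1 and 0; camera adjusted p = 0.345, or adjusted p = 0.569 if estimated). In this comparison 2140 genes differed, 1113 higher and 1027 lower (52.0% higher, 57.2% with library size scaling, 49.98% with RLE). A fit of only these 2 groups gave 1326 genes. The count was 1365 without med23 replicate 1, 1203 without med23 replicate 2, 1152 without med23 ref4-3 replicate 3 and 1377 without med23 ref4-3 replicate 4, and the call of AT2G24210 was lost without med23 replicate 4 (log2 change −2.09).

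For med2, med16 and med23 the change from ref4-3 to the double mutant was set against the change from WT to the single mutant, as a difference of log2 changes ± standard error. The alleles of the single and the double differ, so this mixes allele and background. For med2 it was negative for F3H (−1.57 ± 0.16), UGT84A2 (−1.04 ± 0.12), COR15A (−3.68 ± 0.25), COR15B (−3.58 ± 0.31), TOC1 (−0.53 ± 0.10) and MAF5 (−3.85 ± 0.47) and positive for HCT (0.74 ± 0.08), IAA6 (2.77 ± 0.32) and IAA19 (2.06 ± 0.27) (highest adjusted p = 5.27e-05). On the flavonoid list 0 genes were positive, 18 were negative and 5 of 23 were not called (adjusted over the list alone, 0 and 19; camera adjusted p = 5.94e-14, or adjusted p = 0.0391 if estimated). Cold genes were positive in 0, were negative in 7 and were not called in 8 of 15 cases (adjusted over the list alone, 0 and 10; camera adjusted p = 1.41e-07, or adjusted p = 0.0391 if estimated). For flower markers, 1 of 7 were positive and 4 negative (adjusted over the list alone, 1 and 4; camera adjusted p = 0.0775, or adjusted p = 0.457 if estimated). Of 9 trichome and stomatal markers 0 were positive and 2 negative (0 and 2; adjusted p = 0.261, or adjusted p = 0.457 if estimated). In all, 4445 genes had such a difference, 2528 positive and 1917 negative (56.9% positive, 40.3% with library size scaling).

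For med16 the difference was negative for F3H (−1.50 ± 0.16), UGT84A2 (−1.12 ± 0.11), PBS3 (−2.12 ± 0.24) and WRKY70 (−1.83 ± 0.21) and positive for HCT (0.86 ± 0.08), IAA19 (2.63 ± 0.25), RCA (0.70 ± 0.06) and MED16 (3.87 ± 0.14) (highest adjusted p = 1.32e-08). On the salicylic acid defence list 0 genes were positive, 22 were negative and 3 of 25 were not called (adjusted over the list alone, 0 and 24; camera adjusted p = 1.36e-13, or adjusted p = 0.0853 if estimated). On the photosynthesis list 22 genes were positive, 0 were negative and 0 of 22 were not called (adjusted over the list alone, 22 and 0; camera adjusted p = 7.79e-17, or adjusted p = 0.0476 if estimated). Of 7 flower markers 3 were positive and 0 negative (adjusted over the list alone, 3 and 0; camera adjusted p = 0.0700, or adjusted p = 0.532 if estimated). Among trichome and stomatal markers 1 of 9 were positive and 1 negative (0 and 1; adjusted p = 0.510, or adjusted p = 0.607 if estimated). The root marker was negative (−1.13). In all, 6300 genes had such a difference, 3335 positive and 2965 negative (52.9% positive, 34.6% with library size scaling).

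For med23 the difference was negative for F3H (−1.65 ± 0.16), UGT84A2 (−1.23 ± 0.12), WRKY70 (−1.51 ± 0.23), GRX480 (−4.59 ± 0.67) and MYC2 (−2.07 ± 0.30) and positive for CAD4 (0.77 ± 0.08), IAA19 (2.86 ± 0.24), RCA (0.55 ± 0.06) and MED23 (3.90 ± 0.16) (highest adjusted p = 1.68e-06). On the jasmonate and ethylene list 0 genes were positive, 15 were negative and 3 of 18 were not called (adjusted over the list alone, 0 and 17; camera adjusted p = 9.30e-09, or adjusted p = 0.112 if estimated). Among 22 photosynthesis genes, 19 were positive, 0 were negative and 3 were not called (adjusted over the list alone, 20 and 0; camera adjusted p = 5.66e-10, or adjusted p = 0.112 if estimated). Among flower markers 0 of 7 were positive and 2 negative (adjusted over the list alone, 0 and 4; camera adjusted p = 0.213, or adjusted p = 0.533 if estimated). 0 of 9 trichome and stomatal markers were positive and 2 negative (0 and 2; adjusted p = 0.476, or adjusted p = 0.561 if estimated). The root marker was negative (−0.95). In all, 7067 genes had such a difference, 3575 positive and 3492 negative (50.6% positive, 34.1% with library size scaling).

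Across the 10 groups, 22 genes were above 5 CPM in all 4 libraries of some group and under 0.5 CPM in all 4 of another. AT5G35935 was of this kind: under that level in WT, med5b-3 ref4-3 and med16 ref4-3 and above the upper level in the other 7 groups. This set was chosen after its values were seen.

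**Figure D4:**
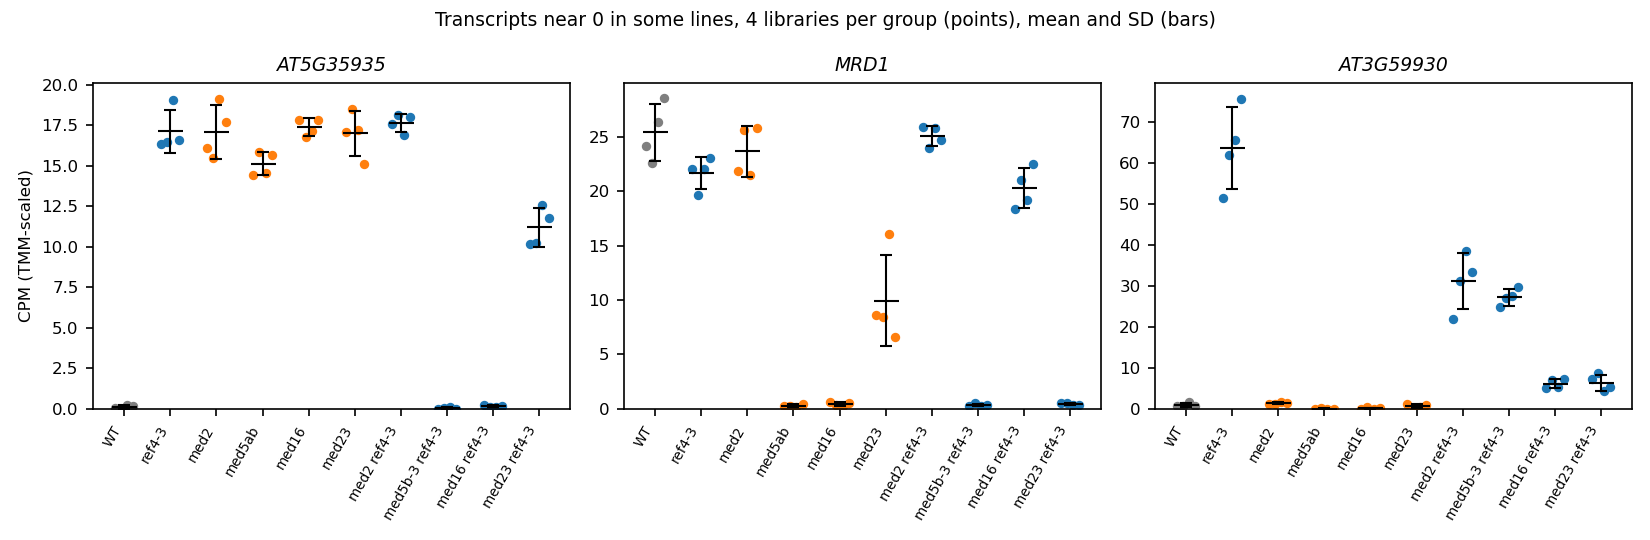
CPM of AT5G35935, MRD1 and AT3G59930, which are near 0 in all 4 libraries of some group and abundant in all 4 of another.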

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

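The test for a library apart, chosen before the data were examined, compares the gap to the nearest of the other 3 libraries of its group with the group's range, and about 1 in 20 groups passes it by chance. It picked out 8 of 80 group and measure pairs (10%): med2 ref4-3 replicate 1 (summary entries 21.8%, chloroplast genes 1.84%, mitochondrial genes 0.169%), WT replicate 4 (alignments to several places 3.76%, chloroplast genes 0.0427%, mitochondrial genes 0.0118%), ref4-3 replicate 1 (alignments to several places 2.57%, mitochondrial genes 0.00900%). Of the targeted genes, 3 of 50 passed (6%): MED16 at 28.2 CPM in ref4-3 replicate 4, 19.8 CPM in med2 replicate 4 and 19.0 CPM in med23 ref4-3 replicate 3. Of the named genes, 38 of 524 passed (7.25%), listed here in CPM.

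In CPM, med2 ref4-3 replicate 1 had ATCG00270 731, ATCG00020 3962, ATCG00100 57.9, ATCG00690 73.3, ATCG00680 625, ATCG00350 1157, ATCG00560 45.2 and ATCG00520 94.6. Library med16 replicate 2 had SOC1 57.4, TAT3 317, MDHAR 22.1 and EXLB1 0.0659. Library WT replicate 4 had MAM3 9.60, CYP79F2 8.95 and XCP2 39.3. Library med5ab replicate 2 had PAL4 20.6, WRKY18 5.26 and SEN1 11.9. Library med23 replicate 2 had KFB-CHS 94.96, AT2G01008 2.55 and CAF1a 4.39. Library ref4-3 replicate 2 had RBCS1B 814 and ATCG00100 0.195. Library ref4-3 replicate 4 had WAK3 14.5 and AT5G57760 0.0481. Library WT replicate 3 had KIN2 77.3 and AT3G59930 1.73. Library ref4-3 replicate 1 had PUB19 14.9 and GolS2 19.3. Library med23 ref4-3 replicate 4 had HCT 178 and AT4G22513 17.2. Library ref4-3 replicate 3 had AT5G35935 19.1. Library med5ab replicate 1 had AOC1 46.5. Library med16 replicate 1 had LTI30 0.570. Library med23 ref4-3 replicate 1 had AT5G57760 9.42. Library med5b-3 ref4-3 replicate 1 had SEN1 9.81. Library med5b-3 ref4-3 replicate 3 had PCC1 35.7. Library med23 replicate 1 had TPS04 8.82.

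The tests in this paragraph were chosen after the counts were seen. The libraries of each comparison were regrouped in every way, 35 in all, or in 100 draws for an interaction, with a fit of only those libraries. 1 of the 35, or 1 of the 100, gave a count as large, the real one. For 2 groups 1 of 35 is the lowest share possible and cannot exclude chance. For interactions, regrouping 4 genotypes moves their differences into the residual, so these splits decide nothing there. The real count and the highest of the others were 7593 and 0 for ref4-3 vs WT, 4292 and 0 for med2 vs WT, 2923 and 0 for med5ab vs WT, 4652 and 0 for med16 vs WT and 204 and 5 for med23 vs WT. Next came 8891 and 0 for med2 ref4-3 vs ref4-3, 8791 and 0 for med5b-3 ref4-3 vs ref4-3, 8254 and 0 for med16 ref4-3 vs ref4-3, 8834 and 0 for med23 ref4-3 vs ref4-3 and 4008 and 0 for med2 ref4-3 vs WT. The values were 2923 and 0 for med5b-3 ref4-3 vs WT, 1845 and 11 for med16 ref4-3 vs WT, 1478 and 2 for med23 ref4-3 vs WT, 1460 and 0 for med2 ref4-3 vs med2 and 5530 and 0 for med5b-3 ref4-3 vs med5ab. After these came 2470 and 0 for med16 ref4-3 vs med16, 1326 and 8 for med23 ref4-3 vs med23, 3852 and 3822 for med2 by ref4-3, 5981 and 1 for med16 by ref4-3 and 6267 and 3 for med23 by ref4-3. With all libraries in the fit, the interactions held for 4445 genes (med2 by ref4-3), 6300 genes (med16 by ref4-3) and 7067 genes (med23 by ref4-3), where allele and background differ together.

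The snoRNA test was chosen before, and the others after, the pattern was seen. Alignments to several places, which the comparisons do not use, made up 18.6% in med2 ref4-3 replicate 1 (next highest 5.83%), where 74 chloroplast genes had a median log2 ratio of 4.75 to the other 3 libraries, and 2 of the 4 med2 ref4-3 libraries lay inside the chloroplast share of the other 36. This library's excess over its group thus cannot come from the genotype alone. The group's replicate 4 (0.0787%) passed the 36 (highest 0.0611%), but replicate 4 was highest in most groups, so a smaller genotype rise is undecided. Ribosomal RNA left in this library would raise nuclear rRNA genes, whose median log2 ratio was 2.47 (highest of the other libraries 0.65). Less poly(A) selection would raise the 23 snoRNA genes, whose ratio was 0.0537, under the bound of 0.25 set beforehand for rejecting it, a verdict set aside after the result was seen because their median level is 1.06 CPM. For genomic DNA, 2.84% of alignments lay outside genes (next highest 2.39%), a rise of 1.43 points against 1.80 for chloroplast genes, which leaves it open.

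The test of neighbours was chosen before, and the others after, the pattern was seen. AT5G35935 is at most 0.225 CPM in WT and 0.248 in med16 ref4-3 but at least 16.4 in ref4-3 and med16. If lesions set its level, which was not tested, each acting alone would have left it on in med16 ref4-3, although the med16 alleles differ. Of 21 other such genes, 0 of 4 readable cases had a double opposite to both parents, too few to tell. MRD1 in med23 ref4-3 (at most 0.573 CPM, parents at least 6.59) just missed. A gain or loss of adjacent genes would move the 88 neighbours, whose median log2 change was 0.19 in size, 11 at 1 or more.

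The test of all 24 matchings was chosen before, and the others after, the pattern was seen. MED2, MED16 and MED23 keep much of their transcript in the double mutants. MED16 was at least 80.7% of the WT mean in all 16 double mutant libraries, so an exchange of med16 ref4-3 with another double cannot account for its level, and MED23 was at least 90.9% in the 12 libraries of the other doubles against at most 43.3% in med23 ref4-3, which rules out an exchange of that line. Of the 24 matchings of doubles to singles, 3, the labelled one included, reached its sum of correlations (0.75, highest other 1.27). MED2 was at least 78.5% in the other doubles, above the highest med2 library (62.2%), so an exchange cannot account for the MED2 level of med2 ref4-3. Its exchange with med5b-3 ref4-3 stays open. Of the 6 orders MED23 allows, the labelled one had the highest sum (next 0.533, that exchange 0.0925). Alleles that leave a transcript in place may account for the MED16 level of at least 80.7%, but allele and ref4-3 background change together.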

How the results depend on the processing

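The settings in this part were chosen before the data were examined, apart from the 3 fits without libraries in doubt. No gene or list call reversed past its threshold in any setting. All 17 counts of changed genes and the 3 interaction counts stayed within 1.5 times under RLE or library size scaling, both filters, DESeq2, limma-voom and a robust dispersion, and without the libraries in doubt. The counts fell by over 1.5 times with a stricter threshold, which calls fewer genes by construction. With at least a 2-fold change required they were 1457 for ref4-3 vs WT, 478 for med2 vs WT, 401 for med5ab vs WT, 958 for med16 vs WT and 49.0 for med23 vs WT. There were also 1368 for med2 ref4-3 vs ref4-3, 1267 for med5b-3 ref4-3 vs ref4-3, 1275 for med16 ref4-3 vs ref4-3, 1726 for med23 ref4-3 vs ref4-3 and 672 for med2 ref4-3 vs WT. Others were 338 for med5b-3 ref4-3 vs WT, 313 for med16 ref4-3 vs WT, 263 for med23 ref4-3 vs WT, 491 for med2 ref4-3 vs med2 and 857 for med5b-3 ref4-3 vs med5ab. It was 396 for med16 ref4-3 vs med16, 152 for med23 ref4-3 vs med23, 789 for med2 by ref4-3, 1522 for med16 by ref4-3 and 1612 for med23 by ref4-3. With adjusted p < 0.01 the counts that moved that far were 3372 for med2 vs WT, 2035 for med5ab vs WT, 3742 for med16 vs WT, 182 for med23 vs WT and 3444 for med2 ref4-3 vs WT. Further counts were 2658 for med5b-3 ref4-3 vs WT, 1504 for med16 ref4-3 vs WT, 1775 for med23 ref4-3 vs WT, 875 for med2 ref4-3 vs med2 and 3776 for med5b-3 ref4-3 vs med5ab. The last were 1106 for med16 ref4-3 vs med16, 835 for med23 ref4-3 vs med23 and 2774 for med2 by ref4-3.

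Genes that moved the same way in 2 mutants numbered, with a 2-fold change, with adjusted p < 0.01 and with the WT libraries split 2 and 2, 102, 753 and 802 for ref4-3 and med2, 82.0, 539 and 559 for ref4-3 and med5ab, 358, 1263 and 1302 for ref4-3 and med16 and 22.0, 83.0 and 85.2 for ref4-3 and med23. These counts were 117, 841 and 813 for med2 and med5ab, 203, 1461 and 1444 for med2 and med16, 12, 89.0 and 89.0 for med2 and med23 and 125, 858 and 800.5 for med5ab and med16. The last were 28.0, 153 and 150.3 for med5ab and med23 and 29.0, 135 and 134 for med16 and med23. With only the libraries of the groups compared, the counts were 204 for med23 vs WT, 1478 for med23 ref4-3 vs WT, 1326 for med23 ref4-3 vs med23, 94.0 for ref4-3 and med23, 106 for med2 and med23, 179 for med5ab and med23, 151 for med16 and med23. Fewer libraries enter these fits and splits.

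Leaving out 1 library at a time moved the 4 counts of genes in opposite ways with med23, given above, by over 1.5 times, and 5 others: med23 vs WT (239 to 374), med2 ref4-3 vs med2 (1124 to 1594), med23 ref4-3 vs med23 (1152 to 2323), med2 and med23 (130 to 206), med5ab and med23 (205 to 328). Of 187 list calls, 22 remained with an estimated correlation, 164 with fry, 183 with library size scaling and 187 with RLE. The median share of the ref4-3 change left moved by more than its leave-one-out spread in med16 ref4-3 with library size scaling, in med5b-3 ref4-3 and med16 ref4-3 without WT replicate 3, and in these and med2 ref4-3 with a 2-fold change required. The cause was not tested.

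Of 403 named gene results, 394 kept their side of the threshold with DESeq2, 397 with limma-voom and 296 with a 2-fold change required. Calls that ended: AT2G24210 (med5ab vs WT), ATCG00560 (med2 ref4-3 vs WT) and AT2G24210 (med23 ref4-3 vs med23) under limma-voom, AT1G07135 (med23 vs WT) and MED2 (med2 ref4-3 vs ref4-3) under only the libraries of the groups compared, ATCG00270, ATCG00100, ATCG00690 and ATCG00680 (med2 ref4-3 vs ref4-3) under DESeq2. MED5B (med5b-3 ref4-3 vs ref4-3) lost the call under no filter except a count above 0, only the libraries of the groups compared and DESeq2. MED2 (med2 ref4-3 vs WT) lost the call under library size alone, no filter except a count above 0 and DESeq2. ATCG00350 (med2 ref4-3 vs WT) and ATCG00270 (med2 ref4-3 vs med2) lost the call under DESeq2 and limma-voom. ATCG00520 (med2 ref4-3 vs med2) lost the call under only the libraries of the groups compared, DESeq2 and limma-voom. Without med2 ref4-3 replicate 1 the calls of MED2 and ATCG00560 (med2 ref4-3 vs WT) and ATCG00520 (med2 ref4-3 vs med2) ended, and without that library and med2 replicate 2 also that of ATCG00270 (med2 ref4-3 vs med2).

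In a fit with a replicate block, all counts stayed within 1.5 times and 1 list call and 1 gene call (MED2 in med2 ref4-3 against WT) ended. In 0 of 45 group pairs did every same-number correlation pass 0.1 (mean 0.00416). Each replicate 4 has later library numbers, so shared sets stay open. The smallest simulated change was called for 48.0% (ref4-3 vs WT) and 18.5% (med2 interaction). Only 200 genes changed per draw, so rates may not carry over.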

Other observations

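Further lists of med2, med5ab, med16 and med23 against WT follow, chosen after their values were seen as those with a camera adjusted p < 0.001 and not given above. In med2, 0 of 16 brassinosteroid genes rose and 7 fell (adjusted over the list alone, 0 and 7; camera adjusted p = 4.66e-04, or adjusted p = 0.0813 if estimated). In med5ab, 0 of 25 salicylic acid defence genes rose and 7 fell (adjusted over the list alone, 0 and 9; camera adjusted p = 9.71e-04, or adjusted p = 0.465 if estimated). In med16, 1 of 22 photosynthesis genes rose and 16 fell (adjusted over the list alone, 1 and 18; camera adjusted p = 7.47e-12, or adjusted p = 0.120 if estimated). In med16, 2 of 24 glucosinolate genes rose and 15 fell (adjusted over the list alone, 2 and 15; camera adjusted p = 1.14e-04, or adjusted p = 0.329 if estimated). In med16, 9 of 18 secondary cell wall genes rose and 0 fell (adjusted over the list alone, 10 and 0; camera adjusted p = 2.05e-04, or adjusted p = 0.190 if estimated).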
